A study of Homo sapiens with 8 samples.

How the data were processed

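RNA-seq was measured in primary human umbilical vein endothelial cells (HUVEC) 48 hours after they received either a synthetic mimic of miR-34a-5p or a scrambled control mimic, with 4 libraries per group. The deposited table of gene counts holds whole numbers, unnormalised, for each library and Ensembl gene. A second deposited table gives the authors' own comparison as a log2 fold change with its confidence limits, together with a p-value and an adjusted p-value for each gene, per the file headers. Per the submitters' processing notes, bcl2fastq, STAR 2.7.9a, Subread, featureCounts 2.0.3, Salmon 1.5.2, edgeR, limma and the genome build GRCh38 were used. Which of these made which file, and the annotation release, are not given in the sources used here.

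The columns of the count table carry short names, a letter pair for the group and a replicate number. They were read as scrambled control mimic and miR-34a-5p mimic with the replicate number of the labels. That reading rests on the names themselves and on the name of the deposited comparison. The table also holds 8 columns of libraries that match no sample of the series, and these were not used here. Of 55209 rows, 116 repeated another gene identifier and were left out, which gave 55093 genes. Nothing in the labels says that the libraries of a group came from separate cultures or donors. The p-values for single genes therefore measure the spread between these libraries alone. Those of the seed tests and of Fisher's exact test are taken across genes. The replicate numbers were not taken to pair the libraries.

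Total counts ran from 22966821 to 33598708 per library. A count of 3, the upper limit that a count of 0 allows, stood for 0.0893 to 0.131 CPM (counts scaled to the library total), and this floor covers counting error alone. Genes were kept with edgeR's filterByExpr by group, which left 18076 tested genes. Libraries were scaled by TMM and compared with edgeR 4.0.16 (quasi-likelihood F test, robust, 2-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each log2 fold change is mimic over control. It is given with its standard error (SE), and CPM are given as mean ± SD over 4 libraries. Principal components were taken from log2 CPM. Software was R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

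The comparison, its test, the gene lists, the seed test and the rule for naming genes were chosen before the data were examined. So were the alternatives, except those named below as added later. The lists were written from general knowledge: published miR-34a-5p targets, DNA replication and G1/S, mitosis and G2/M, replication-dependent histones, senescence-associated secreted factors, endothelial identity, leukocyte adhesion and NF-kB response, type I interferon response, Notch pathway, cell junctions, endothelial-to-mesenchymal transition, VEGF signalling and tip-cell genes, sirtuins and NAD metabolism, apoptosis regulators, oxidative phosphorylation, mitochondrial biogenesis and quality control, glycolysis, cholesterol biosynthesis, unfolded protein and integrated stress response, antioxidant NRF2 response, miRNA processing and RISC, nitric oxide and vascular tone, and markers of smooth muscle and pericytes, fibroblasts, leukocytes, epithelium, erythroid cells and lymphatic endothelium. 1 further list is not reported here. Lists share genes, and several marker genes are also expressed by endothelial cells. Each list was tested with limma's camera (preset inter-gene correlation, 2-sided, adjusted over the 28 lists with a tested member), again with an estimated correlation, and with limma's fry. Fry's main p asks whether the members move, on balance, one way, and its mixed p asks whether they change in either direction. Neither compares the list with other genes.

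Genes were named by rule: the 10 largest rises and the 10 largest falls among protein-coding genes past the threshold with at least 5 CPM in the higher group and no overlap between the groups; up to 4 members of each list with the smallest p; genes fixed by name, among them SIRT1, NOTCH1, CDK6, CCND1, BCL2, MET, CDKN1A, NOS3 and MIR34AHG; and the 5 genes with an 8mer match and the largest fall. Any other gene below was named after its values were seen, mostly where a count was 5 or fewer.

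For the seed test, protein-coding genes were classed by their best match to the miR-34a-5p seed in the longest 3' UTR of GENCODE 29 (GRCh38), a release that may differ from the one behind the counts. Which 3' UTRs HUVEC express was not known, and genes that express a shorter one can be classed by a match they lack. Coordinates come from the same annotation, and symbols come from the deposited table. Differences of mean log2 fold change from genes with no match were tested with 100000 permutations, with 95% bootstrap intervals. For the 8mer, the difference from all genes without the word was also taken. It was compared with that of other 8-base words of the same composition, each held by at least 30 genes. Genes are not independent replicates, so these p-values describe genes and not libraries.

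Alternatives were RLE, upper-quartile and library-size scaling, no filter, at least 1 CPM in 4 libraries, DESeq2, limma-voom, a replicate block, protein-coding genes alone, an absolute log2 fold change of at least 1, each library left out in turn, and, for the seed test, the shortest 3' UTR, length-matched genes, DESeq2 fold changes and genes of at least 5 CPM. Lists were also tested without genes shared with another list. With a library left out the filter was run anew, which left 18282 to 18617 tested genes. The tested members of a list can therefore differ from those with all 8 libraries, and its counts and median with them. Thinning all libraries to the smallest total, and removing the log length of the 3' UTR and its GC content, each with its square, from the seed differences by regression, were added after the data were seen. The pipeline was tested on simulated data with the libraries' own depth and spread. With 50 genes at each size, edgeR called 66% of 2-fold falls, 40% of falls of 0.5 (log2), 48% of rises of 0.5 and 74% of 2-fold rises, and 6 of its 120 calls were false.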

Results

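The series asked which transcripts change when HUVEC, the endothelial cells that line the umbilical vein, carry an excess of miR-34a-5p, a microRNA whose hairpin lies on chromosome 1 (9151668–9151777, minus strand, GRCh38). A mimic is a short synthetic RNA duplex that acts as the mature microRNA. Each group had 4 RNA-seq libraries. Total counts were 28060743, 29652073, 28641596 and 22966821 in the scrambled control libraries 1 to 4 and 27493977, 33598708, 31417435 and 30594041 in the mimic libraries 1 to 4. The first principal component (31.7% of the variance) parted the 4 mimic libraries from the 4 controls, and the second (13.3%) spread the libraries within groups. Pairs of libraries differed more between groups (chi-square per degree of freedom 28.72 to 46.65 over 16 pairs) than within them (3.913 to 13.42 over 12 pairs). Mimic library 4 stood apart in its own group. It had 28675 genes with a count against 26648 to 27460 in the other mimic libraries, and lncRNA took 1.23% of its counts against 0.896% to 0.931%. Genes with a count numbered 26326 ± 310 in the controls and 27411 ± 910 in the mimic libraries (SD, n = 4). The exact permutation p was 0.0286, 2-sided, the smallest that 4 against 4 allows. Deeper libraries detect more genes, and thinning all libraries to the smallest total took the mean difference from 1085 to 889 genes. Thinned, mimic library 4 had 28259 genes and the other mimic libraries 26402 to 26801, against 25901 to 26350 in the controls.

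With the mimic, HUVEC lowered most published miR-34a-5p targets, the replication and mitosis programmes and all 29 tested replication-dependent histone genes. More apoptosis regulators, NF-kB response genes and VEGF signalling genes rose than fell. As lists, these passed with the preset correlation of camera and none passed with an estimated one. Endothelial identity genes went both ways. Of 18076 tested genes, 5620 passed the threshold (31.09%), 2748 up and 2872 down. Changes of at least 1 on the log2 scale were mostly rises, 333 against 107 falls. Protein-coding genes made up most calls (2538 up and 2735 down of 13365), and lncRNA had 133 up and 50 down of 2159 (96 up and 51 down of 2213 without mimic library 4). The 4 mimic and the 4 control values did not overlap for 5455 genes, 30.2% of those tested, where chance gives 2.86%.

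The largest rises by the naming rule were SULF1 (log2 fold change 3.29), LTB (3.21), CX3CL1 (3.18), CD69 (3.01), DAPK2 (2.41), TNFRSF4 (2.37), RCSD1 (2.35), ITGA9 (2.21), ABCA4 (2.12) and CA8 (2.06). CD69 (ENSG00000110848, chromosome 12, 9752486–9760901) had the smallest p of all genes and went from 7.64 ± 1.19 to 61.1 ± 2.48 CPM (SD, n = 4; SE of the log2 fold change 0.09, adjusted p = 1.1e-20). The chemokine gene CX3CL1 (ENSG00000006210, chromosome 16, 57372458–57385048) went from 11.2 ± 2.87 to 100.4 ± 29.2 CPM (SE 0.30, adjusted p = 0.00025). The largest falls were DNER (-2.17), CXCL10 (-1.68), SYT1 (-1.64), DLL1 (-1.52), BHLHA15 (-1.51), PLXNA4 (-1.50), CBLN2 (-1.47), SULT1B1 (-1.45), MET (-1.33) and LAMA1 (-1.31). The receptor gene MET (ENSG00000105976, chromosome 7, 116672390–116798386) went from 241.9 ± 8.54 to 96.5 ± 7.84 CPM (SE 0.05, adjusted p = 3.8e-17).

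Most published miR-34a-5p targets fell. Of 49 tested, 33 fell, 4 rose and 12 did not pass (34 down and 6 up adjusted over the list alone). Their median log2 fold change was -0.48, and the list lay below other genes (camera adjusted p = 7.0e-11; adjusted p = 0.0688 with an estimated correlation). FOSL1 (ENSG00000175592, chromosome 11, 65892049–65900573) fell by 1.29 (SE 0.05), from 251.9 ± 16.7 to 102.7 ± 5.94 CPM (adjusted p = 5.9e-17). NOTCH2 (-0.96), CDK6 (-0.92), ACSL4 (-0.83), NOTCH1 (-0.70) and CCND1 (-0.21) fell as well. The deacetylase gene SIRT1 (ENSG00000096717, chromosome 10, 67884669–67918390) went from 26.0 ± 2.01 to 18.6 ± 1.93 CPM, a log2 fold change of -0.48 (SE 0.09, adjusted p = 7.3e-05). BCL2 did not pass (0.09, adjusted p = 0.765), nor did the host transcript of the microRNA, MIR34AHG (-0.16, adjusted p = 0.845; 0.765 ± 0.374 CPM in controls). The 4 published targets that rose were TCF7, CD44, SNAI1 and CD274. Without control library 3, 2 targets rose.

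**Figure D1:**
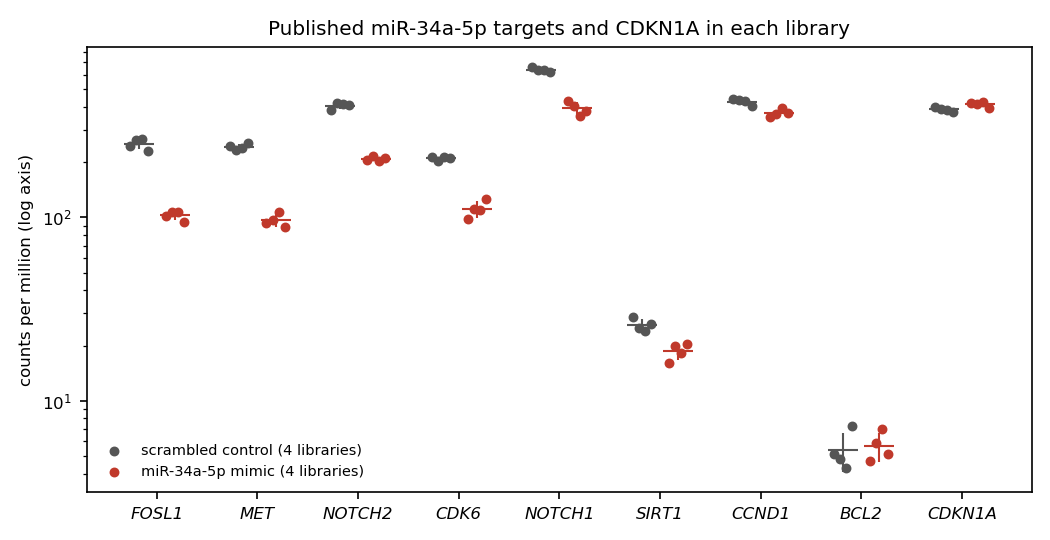
CPM (log axis) of 8 published miR-34a-5p targets and CDKN1A in each library, grey for control and red for mimic, with lines at the group mean and ± SD (n = 4). FOSL1, MET, NOTCH2, CDK6, NOTCH1, SIRT1 and CCND1 lay lower in all 4 mimic libraries than in any control, while BCL2 and CDKN1A did not pass the threshold.

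The direct readout of the mimic is whether transcripts with a match to its seed went down. They did for the 8mer and the 7mer-A1, and for the other classes once length and GC content of the 3' UTR were removed. Among 13266 genes with an annotated 3' UTR, 804 held the 8mer CACTGCCA. Their mean log2 fold change lay 0.12 below that of the 8602 genes with no match (difference -0.12, 95% interval -0.15 to -0.08; permutation p = 1e-05, 2-sided, the smallest that 100000 resamples can give; adjusted over the 4 classes, 4e-05). With the shortest annotated 3' UTR of each gene, where 318 genes held the 8mer, the difference was -0.18. Of the 8mer genes of the longest 3' UTR 32.84% fell, against 18.31% with no match. Genes with the 7mer-A1 differed by -0.07 (814 genes, 28.26% fell; permutation p = 4e-05, adjusted 8e-05). Genes whose best match was the 7mer-m8 (1562 genes, -0.01; permutation p = 0.25) or the 6mer (1484 genes, -0.02; permutation p = 0.068, adjusted 0.091) were not shown to differ in this comparison. The 3' UTRs without a match were shorter (median 936 bases against 2420.5 for the 7mer-m8). A regression that removed length and GC content, chosen after the data were seen, gave -0.16 for the 8mer, -0.09 for the 7mer-A1, -0.07 for the 7mer-m8 (95% interval -0.09 to -0.04) and -0.05 for the 6mer (-0.07 to -0.03). With length alone removed the 7mer-m8 gave -0.029 (95% interval -0.054 to -0.0048), and the interval reached 0 without control library 1 (-0.048 to 0.0033) or mimic library 3 (-0.050 to 0.0011). The share that fell was 18.61% with no 7- or 8-base match, 25.47% with 1, 29.57% with 2 and 23.5% with 3 or more. In a scan of 16371 words of 7 bases, with length and GC content removed and the 8mer genes counted under both words, the pair of miR-34a-5p seed matches had the most negative scores, ACTGCCA (z = -9.73) and CACTGCC (z = -7.81). The 8mer genes with the largest falls were CXCL10, SYT1, AMER1 (-1.31), FOSL1 and F2RL2 (-1.26). Of the published targets 42 of 49 held a 7- or 8-base match, 26 of the 33 that fell and all of the others.

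**Figure D2:**
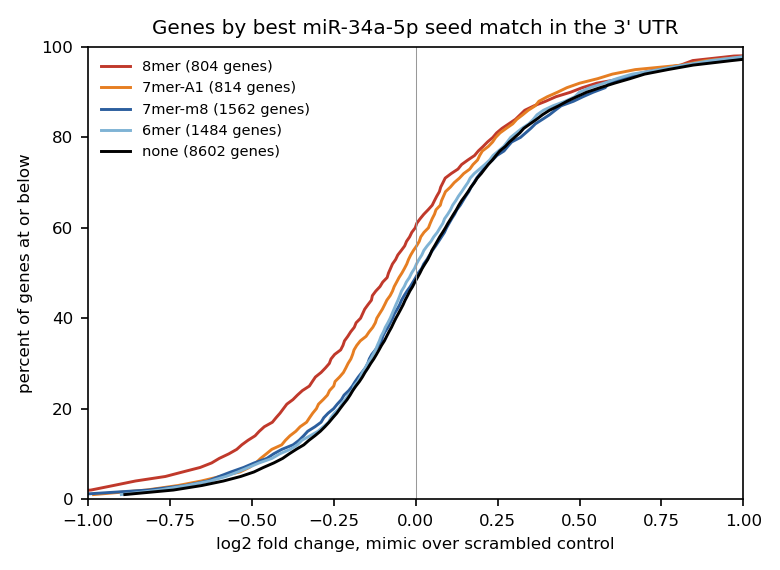
Cumulative percent of genes (y axis) at or below each log2 fold change (x axis) for genes grouped by their best miR-34a-5p seed match in the 3' UTR. The curve of the 804 genes with an 8mer lay to the left of the curve of the 8602 genes with none up to the 98th percentile.

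The cell-cycle programme fell almost whole. All 35 mitosis and G2/M genes fell (35 adjusted over the list alone, median -0.58, camera adjusted p = 1.2e-21; adjusted p = 0.0871 with an estimated correlation), with FOXM1 (-0.70), PLK1 (-0.74), TPX2 (-0.60) and HMMR (-1.03) among them. Of 36 DNA replication and G1/S genes, 34 fell and 2, CCNE1 and CCNE2, did not pass (35 down adjusted over the list alone, median -0.57, camera adjusted p = 3.0e-18; adjusted p = 0.0871 with an estimated correlation). MCM2 (-0.65), MCM3 (-0.73), CDC6 (-0.81) and UHRF1 (-0.59) belonged to the fallen. All 29 tested replication-dependent histone genes fell (29 adjusted over the list alone), by a median of -0.78 (camera adjusted p = 1.8e-20; adjusted p = 0.211 with an estimated correlation), H2BC18 by -0.96 and H4C9 by -0.93. Few of these genes held a 7- or 8-base seed match. They were 4 of the 35 mitosis genes, 5 of the 34 fallen replication genes and 1 of the 15 classed histone genes. Of all classed genes 23.97% held one. These shares were not adjusted for 3' UTR length, and genes with no match had shorter 3' UTRs (median 936 bases against 2667 for the 8mer).

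Apoptosis regulators leaned up. Of 30, 16 rose, 3 fell and 11 did not pass (16 up and 4 down adjusted over the list alone, median 0.22, camera adjusted p = 0.0017; adjusted p = 0.0688 with an estimated correlation). BBC3 rose by 1.19, from 44.6 ± 1.17 to 101.5 ± 8.72 CPM (SD, n = 4, adjusted p = 3.7e-15). BCL2L11 (1.42) and PMAIP1 (0.70) rose, and so did BMF (1.96), while BIRC5 (-0.60), CYCS (-0.44) and BCL2A1 (-0.47) fell. Senescence-associated secreted factors were mixed: 14 rose, 7 fell and 14 did not pass (15 up and 7 down adjusted over the list alone, median 0.13, camera adjusted p = 0.0374; adjusted p = 0.594 with an estimated correlation). MMP10 (1.62), CCL2 (0.71), IGFBP7 (0.78) and TIMP2 (0.66) rose and IL6 (-0.36) fell. That list missed the threshold without mimic library 3 (adjusted p = 0.052), without genes shared with another list (0.134) and with a replicate block (0.0734), and its median was 0.08 without control library 3. The cell-cycle inhibitor gene CDKN1A held 387.0 ± 10.4 CPM in controls and 413.7 ± 13.7 with the mimic (0.10, SE 0.04, adjusted p = 0.092). It passed without mimic library 4 (adjusted p = 0.0173) and with upper-quartile scaling (0.0189), the stricter filter (0.0374) or protein-coding genes alone (0.0474).

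Most NF-kB response and leukocyte adhesion genes rose. Of 25 NF-kB and adhesion genes, 17 rose, 2 (IL6 and TNFAIP3) fell and 6 did not pass (17 up and 2 down adjusted over the list alone, median 0.45, camera adjusted p = 7.2e-07; adjusted p = 0.22 with an estimated correlation). CD69, CX3CL1, NFKB2 (0.75), CCL2 and TRAF1 (0.68) were among the risen. Without mimic library 2 or 3, 1 of the genes fell. Of 37 type I interferon response genes, 6 fell, none rose and 31 did not pass (5 down adjusted over the list alone, median -0.20, camera adjusted p = 0.0086; adjusted p = 0.863 with an estimated correlation). The fallen were CXCL10, EPSTI1 (-0.82), IFIT1 (-0.74), HERC6 (-0.64), MX1 (-0.46) and OAS3 (-0.45). CXCL10 (ENSG00000169245, chromosome 4, 76021117–76023497) went from 72.2 ± 11.7 to 22.4 ± 10.0 CPM (adjusted p = 0.0076).

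The interferon result hung on single libraries. Relative to the control mean, the median of the 37 genes was -0.52, -0.30 and -0.25 in mimic libraries 1 to 3 but 0.17 in mimic library 4, where 9 of 37 genes lay below the control mean. Without mimic library 4, 23 of the 37 genes fell, the median log2 fold change was -0.35 and the list's adjusted p was 1.3e-07. Without mimic library 1, 8 fell, 4 rose, the median was -0.11 and the list missed the threshold (adjusted p = 0.12). Without mimic library 2, 2 fell, and IFIT1 (adjusted p = 0.0549) and HERC6 (0.0564) missed the threshold. With limma-voom 16 fell.

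**Figure D3:**
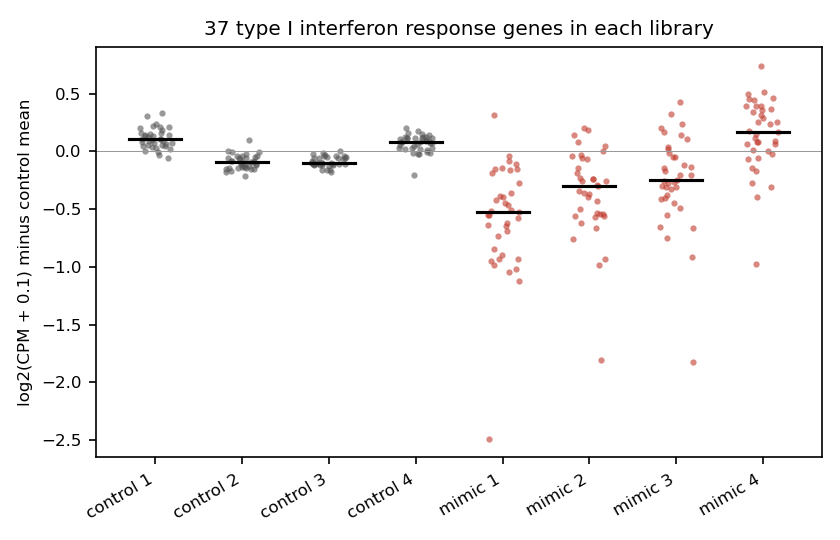
Each point is 1 of 37 type I interferon response genes in 1 library, as log2(CPM + 0.1) minus the mean of the 4 controls (y axis), with a line at the library's median. Mimic libraries 1 to 3 had medians from -0.52 to -0.25, and mimic library 4 had a median of 0.17.

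VEGF signalling and tip-cell genes leaned up. Of 29, 18 rose, 2 (VEGFC and NRP1) fell and 9 did not pass (20 up and 3 down adjusted over the list alone, median 0.54, camera adjusted p = 7.8e-07; adjusted p = 0.0688 with an estimated correlation). COL4A1 (ENSG00000187498, chromosome 13, 110148963–110307233) went from 1234 ± 84.4 to 3567 ± 282 CPM, a log2 fold change of 1.53 (SE 0.06, adjusted p = 8.6e-15), and its neighbour COL4A2 rose by 1.06. PDGFB (1.04) and PGF (0.77) rose too. The Notch pathway split: DLL1, HEY2, NOTCH1, NOTCH2 and MFNG fell, while 5 rose, DLL4 (1.26), MAML2 (0.70), JAG2 (0.50) and LFNG among them, and 14 of 24 did not pass (5 up and 5 down adjusted over the list alone, median -0.06, camera adjusted p = 0.76, fry adjusted p = 0.0202 on balance, down). Without mimic library 4, 3 Notch genes fell.

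Endothelial identity did not move as a block. Of 33 genes, 9 rose, 8 fell and 16 did not pass (10 up and 9 down adjusted over the list alone). The median was -0.02 (with 1 library left out, from -0.05 without control library 1 to 0.02 without mimic library 4), the mean 0.05 and the test pointed up (camera adjusted p = 0.96, fry mixed adjusted p = 1.1e-06). SOX17 (0.42) and ROBO4 (0.58) rose while THBD (-0.92) and GATA2 (-0.47) fell. Among 24 junction genes, 6 rose (JUP 1.03, GJA1 0.50 and CDH5 0.33 among them), 3 fell (CLDN11, MARVELD2 and CGN) and 15 did not pass (7 up and 3 down adjusted over the list alone, camera adjusted p = 0.754). Without control library 1, 5 junction genes fell. For nitric oxide and vascular tone, 6 of 20 rose, 5 fell and 9 did not pass (7 up and 6 down adjusted over the list alone), with a median of -0.03 (with 1 library left out, from -0.09 without control library 1 to 0.01 without mimic library 3) and a mean of -0.08 although the test pointed up (camera adjusted p = 0.924). EDN1 (0.48), DDAH1 (0.26) and DDAH2 (0.44) rose, and NOS3, EDNRB, GCH1, KLF2 and HSP90AA1 fell. NOS3 went from 64.8 ± 9.30 to 41.4 ± 8.04 CPM (-0.65, adjusted p = 0.0216), and missed the threshold without mimic library 2 (adjusted p = 0.0606) or 3 (0.0507). Without mimic library 2, 3 genes of the list fell.

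More genes of endothelial-to-mesenchymal transition rose than fell. Of 25, 9 rose, 2 (TWIST2 and CCN2) fell and 14 did not pass (11 up and 2 down adjusted over the list alone, median 0.15, camera adjusted p = 0.004; adjusted p = 0.194 with an estimated correlation). TPM1 (0.89), COL5A1 (0.84), MYL9 (0.63) and TGFBR1 (0.59) rose. The median was 0.32 without control library 1, 0.31 without control library 2 and 0.10 without control library 3. It was 0.36 without mimic library 2, 0.27 without mimic library 3 and 0.37 without mimic library 4. The tested members can differ between these fits, so the shifts cannot be laid to the libraries alone. Without mimic library 2, 1 gene fell. Markers of other cells showed no common rise. Of 8 smooth muscle and pericyte markers, MCAM rose (0.35), RGS5 (-0.74) and SMTN (-0.35) fell and 5 did not pass, with the same counts adjusted over the list alone. Their median was 0.08 (with 1 library left out, from -0.07 without mimic library 2 to 0.12 without control library 3) and their mean -0.06, and the test pointed down (camera adjusted p = 0.76). None of 6 fibroblast markers passed, adjusted over the list alone or over all genes (median 0.08, or with 1 library left out from -0.09 without mimic library 2 to 0.41 without control library 1, mean 0.11, test down, camera adjusted p = 0.96). COL3A1 (0.65, adjusted p = 0.379) and FBLN1 (0.26, adjusted p = 0.782) had the smallest p. Without control library 2 or mimic library 3, 1 fibroblast marker rose. Neither of the leukocyte markers tested passed (camera adjusted p = 0.96). CSF1R was at 0.24 (adjusted p = 0.747), and LCP1 at -0.45 (adjusted p = 0.266) passed without mimic library 3 (-0.85, adjusted p = 0.0073). Of 7 epithelial markers, KRT19 (-0.94), CLDN7 (-0.45) and KRT18 (-0.37) fell, also adjusted over the list alone, and 4 did not pass (median -0.45, camera adjusted p = 0.0439; adjusted p = 0.4 with an estimated correlation). This call was lost without control library 1 (adjusted p = 0.065), 2 (0.061) or 4 (0.0657) or mimic library 4 (0.0848, median -0.27). CLDN7 missed the threshold without mimic library 3 (0.0693) or 4 (0.0682), and KRT18 without control library 2 (0.0658), 3 (0.068) or 4 (0.0574) or mimic library 2 (0.0702). Of 5 lymphatic markers, FLT4 rose (0.81), LYVE1 fell (-1.13, adjusted p = 0.0356) and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.96). LYVE1 missed the threshold without control library 2 (adjusted p = 0.145) or 4 (0.0507) or mimic library 2 (0.109) or 3 (0.0659), and with no filter (0.0706). None of 9 erythroid markers had counts enough to be tested.

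Glycolysis genes and mitochondrial genes leaned down with the preset correlation. Of 22 glycolysis genes, 13 fell, 4 (SLC16A3, PFKL, SLC2A3 and PFKFB3) rose and 5 did not pass (13 down and 4 up adjusted over the list alone, median -0.21, camera adjusted p = 0.0045; adjusted p = 0.594 with an estimated correlation). HK2 (-0.74), LDHA (-0.63), GAPDH (-0.60) and TPI1 (-0.53) fell. Without control library 1 or 4 or mimic library 3, 2 glycolysis genes rose. Of 51 oxidative phosphorylation genes, 12 fell, COX4I1 rose and 38 did not pass (10 down and 1 up adjusted over the list alone, median -0.10, camera adjusted p = 0.0213; adjusted p = 0.804 with an estimated correlation). ATP5MC1 (-0.47), ATP5PB (-0.27), SDHB (-0.25) and CYCS fell. The count of rises was 0 without control library 2, 3 or 4 or mimic library 3, and 2 without mimic library 4. Of 31 genes of mitochondrial biogenesis and quality control, 11 fell (HSPD1 -0.52, TFAM -0.46, DNM1L -0.43 and MFN2 -0.41 among them), SOD2, PINK1, POLG and BNIP3L rose and 16 did not pass (11 down and 5 up adjusted over the list alone, median -0.09, camera adjusted p = 0.0421; adjusted p = 0.629 with an estimated correlation). Without mimic library 4 both mitochondrial lists missed the threshold (adjusted p = 0.152 for oxidative phosphorylation and 0.118 for biogenesis, with a median of -0.06 for the latter). The oxidative phosphorylation median was -0.15 without control library 4.

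Stress and metabolic lists had members that rose and members that fell. Of 30 unfolded protein and integrated stress response genes, 13 fell, 6 rose and 11 did not pass (13 down and 8 up adjusted over the list alone, camera adjusted p = 0.0623). XBP1 (-0.67), SHMT2 (-0.51) and TRIB3 (-0.48) fell and DDIT4 rose (1.54). This list passed without control library 2 (adjusted p = 0.0428), 3 (0.0383) or 4 (0.0407) or mimic library 3 (0.0171), with library-size scaling (0.0471) and without genes shared with another list (0.0407). Of 24 cholesterol biosynthesis genes, 4 fell, STARD4 (-0.60) and MSMO1 among them, LSS (0.24) and FDPS (0.21) rose and 18 did not pass (4 down and 2 up adjusted over the list alone, median -0.19, camera adjusted p = 0.0163; adjusted p = 0.633 with an estimated correlation). Without control library 1, 11 fell; without mimic library 1, 7; without mimic library 2, 8; and without mimic library 4 the list missed the threshold (adjusted p = 0.0718, median -0.12). In the NRF2 response, 6 of 22 fell (FTL -0.34 and TXN -0.32 among them), ABCC1 (0.34), GPX1 (0.27) and SLC7A11 rose and 13 did not pass (7 down and 3 up adjusted over the list alone, camera adjusted p = 0.76). Of 19 sirtuin and NAD genes, SIRT1, PARP1 (-0.38), NAMPT (-0.37) and NNT fell, 6 rose, NNMT by 0.45, and 9 did not pass (4 down and 7 up adjusted over the list alone, camera adjusted p = 0.76). Without control library 2 or 4 or mimic library 3, 3 of them rose. Of 17 genes of miRNA processing and the RISC complex, AGO4 (0.84), TNRC6B (0.41), AGO2 (0.38) and AGO3 rose, RAN (-0.32), MOV10, XPO5, TARBP2 and PRKRA fell and 8 did not pass (4 up and 5 down adjusted over the list alone, camera adjusted p = 0.96). AGO4 and TNRC6B rose although their 3' UTRs hold an 8mer, as AGO2 did with a 7mer-m8.

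**Figure D4:**
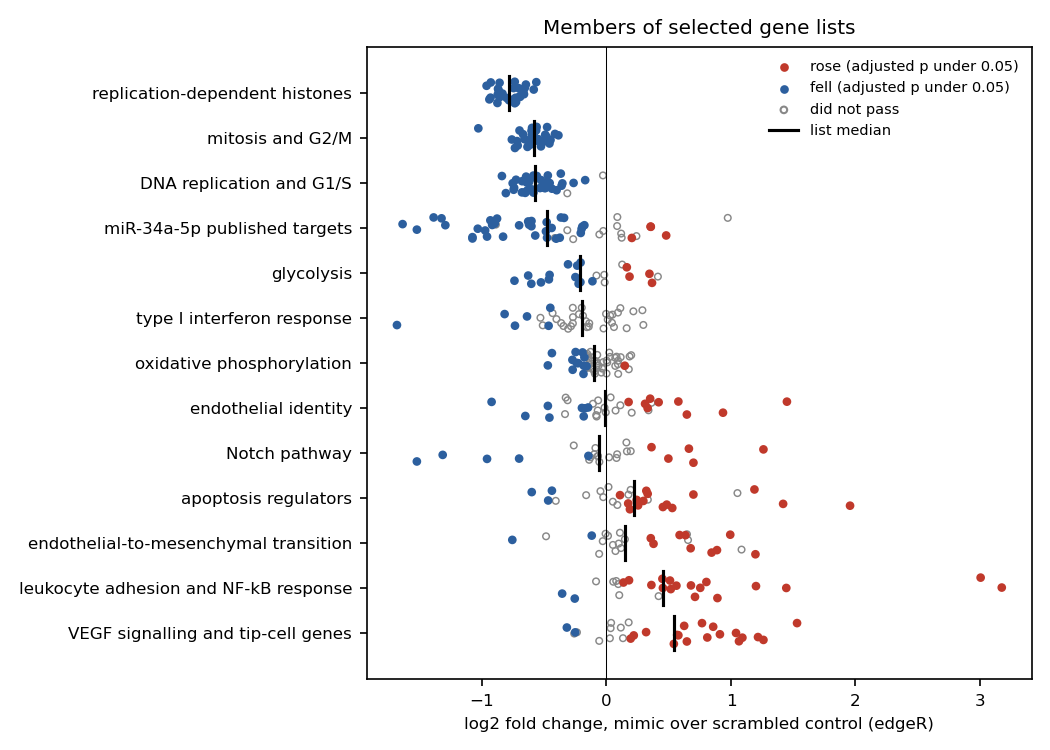
Log2 fold change (x axis) of the members of selected gene lists, red for genes that rose, blue for genes that fell, open for genes that did not pass, with a black line at the list median. Histone, mitosis and replication genes sat left of 0, and VEGF and NF-kB genes mostly right of it.

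Of the 28 lists with a tested member, 16 passed with the preset correlation and 0 with an estimated one, where 7 lists had an unadjusted camera p under 0.05. Fry called 17 lists, among them Notch, junctions (adjusted p = 0.0371), nitric oxide and vascular tone (0.0357) and the unfolded protein response (0.0109), and not interferon (0.29), oxidative phosphorylation (0.105) or cholesterol (0.0729). Fry's direction on balance differed from camera's for fibroblast and lymphatic markers, which passed with neither.

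The authors' deposited table held 15068 genes, of which 6031 had an adjusted p under 0.05, 3011 up and 3020 down. Of the 15065 genes tested in both, 5520 were called here and 5367 in both, all in the same direction, and the log2 fold changes had a Pearson r of 0.981 across genes. Of the named genes, CDKN1A passed in the authors' table (adjusted p = 0.0069) but not here, while CLDN7 (adjusted p = 0.119 in that table) and LYVE1 (0.0741) passed here but not there.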

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

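The tests of Alu repeats, of the 3' UTRs of the 7mer-m8 class, library depth and low expression were chosen after the results they bear on were seen; the tests of 3' UTR length and base composition for the 8mer were planned.

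For each group of 4 libraries, the gap between an extreme library and its nearest neighbour was divided by the group's range, and groups above Dixon's 95% critical value are listed. Of 268 groups (the library measures and 127 named genes), 19 passed, 7.09%, where chance gives about 1 in 20. Mimic library 4 was highest for the lncRNA share of counts (ratio 0.896; 1.23% against at most 0.931%) and for LAMA1 (0.848; 4.82 CPM against at most 3.35), and lowest for TPX2 (0.865; 90.6 against at least 105.4) and BIRC5 (0.895; 40.2 against at least 49.0). Mimic library 1 was lowest for NFKB2 (0.845) and mimic library 3 highest for LCP1 (0.918). Control library 1 was highest for THBD (0.835), SHMT2 (0.836), TRIB3 (0.939) and LCP1 (0.911) and lowest for TIMP2 (0.893) and HSPD1 (0.898). Control library 2 was highest for PLK1 (0.88) and lowest for TP53INP1 (0.837) and CDK6 (0.852), and control library 3 was lowest for F2RL2 (0.919). Control library 4, the smallest, was highest for ABCA4 (0.92), DNER (0.884) and PGF (0.842). No explanation was tested for these single libraries.

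Transcripts with an 8mer match to the miR-34a-5p seed lay lower with the mimic. Long 3' UTRs hold more matches by chance, but against genes matched for length the difference was -0.1354, where length as the cause would have brought it above -0.05. Base composition was argued against as well. Genes with the 8mer differed by -0.1071 from all genes without it. On that measure 0.6188% of the 808 other words of the same bases, 5 words, lay as low. The remaining explanation, repression through the seed, is the one the design names, and these values go with it. Delivery of a mimic was common to both groups. The seed words ACTGCCA (z = -9.73) and CACTGCC (z = -7.81) were the lowest of 16371 words, which argues against delivery alone. Repression through the seed was not tested apart from other effects of the mimic.

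Genes whose best match was the 7mer-m8 were not shown to lie lower than genes with no match (-0.0133). Matches inside Alu repeats could dilute the class, yet only 16 of its 1562 genes (1.02%) had every match in Alu-type sequence. Leaving them out changed the difference by -0.00117 (95% interval -0.00347 to 0.000684), where a hidden fall of 0.05 needed a change of -0.0367. With so few genes left out, a change of that size was hardly possible. The test therefore shows only that few such genes were found. It replaced an earlier form, which could not decide, after its outcome could be foreseen. The remaining genes of the class differed from genes with no match by -0.0145 (95% interval -0.0382 to 0.0095). Length and base composition of the 3' UTR could have hidden the fall, since with both removed by regression the class lay lower (-0.06782, 95% interval -0.09291 to -0.04274). That regression was found and tested on the same genes. No biological explanation was tested.

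Rises of at least 1 on the log2 scale outnumbered falls by 3.11 to 1. Deeper mimic libraries were argued against, since thinning all libraries to 22966821 counts left a ratio of 3.3, and so were genes of low expression as the whole cause, since genes of at least 5 CPM gave 2.82. An indirect response to the mimic stays open and was not tested.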

How the results depend on the processing

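The thinning of libraries and the removal of 3' UTR length and GC content were chosen after the data were seen; every other alternative was planned. The count of 5620 genes lay between 5357 (replicate block) and 5746 (DESeq2) under the other scalings, filters and tools, and at 5535 after thinning. Leaving out 1 library gave 4918 to 5408 genes, 2093 to 2639 up and 2598 to 3099 down. Requiring a change of at least 1 left 440, of which 333 rose and 107 fell, by construction. The share of calls that rose ran from 42.26% to 52.26% against 48.9%, so which direction is more common depended on the setting. The seed difference of -0.1156 was -0.1847 with the shortest 3' UTR and -0.1648 with length and GC content removed. It was -0.1354 against length-matched genes, -0.1156 with DESeq2 fold changes, -0.1221 for genes of at least 5 CPM and -0.1152 with a block. Leaving out 1 library gave -0.1208 to -0.1141, or -0.168 to -0.1611 with length and GC content removed as well. Removing length alone gave -0.1349, and -0.1399 to -0.1279 with a library left out. Of 28 lists, 16 passed as reported, 14 with a block, 12 to 17 with a library left out and 0 with an estimated correlation. The cause of that last loss was not tested, but a higher correlation does not account for all of it. For apoptosis regulators the estimated correlation, 0.00109, lay below the preset one. Their unadjusted camera p still went from 0.00049 to 0.008. The 8 lists that kept their side of the threshold in every setting were all lists that did not pass. With a block, senescence-associated factors (adjusted p = 0.0734) and mitochondrial biogenesis (0.0547) missed the threshold; the cause was not tested. Of 127 genes named by the rule, 118 kept their side everywhere, 9 changed it without 1 library, and LYVE1 also with a block (adjusted p = 0.0594). Genes named outside the rule were followed only through the counts of their lists. The authors' calls shared 5367 genes with edgeR and 5315 with limma-voom. The replicate numbers did not pair the libraries: residual correlations between mimic and control libraries of the same number were -0.0797, 0.0506, -0.0317 and -0.0217, so the block is an alternative and not a correction. Depth and 4 libraries limit small changes. On simulated data, over genes of all levels, 40% of falls and 48% of rises of 0.5 were called. The simulation gave 120 calls against 5620 here, and fewer calls make the adjusted threshold stricter. These shares may therefore understate how many such changes were called here. A gene that did not pass and has a large SE may still have changed by that much.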

Other observations

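The tests of interferon genes and of symbol families were chosen after the results were seen; the tests of library splits, of the opposite strand and of a control seed were planned.

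The 8 libraries can be split into 4 and 4 in 35 ways. With edgeR, 1 of the 35 splits gave as many genes past the threshold, the real one, with 5620, and the highest of the others was 0. At an unadjusted p under 0.05 the real split gave 7092 genes and the others 202 to 1677. The calls thus went with the real grouping alone, at 1 in 35, the smallest share that these splits allow. Every other split mixed mimic and control libraries, which widens the spread within its groups. Their counts therefore do not show what libraries without a treatment difference would give.

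The strand opposite the mimic's guide could also repress transcripts. Its sequence is not given in the sources used here, and that of miR-34a-3p was taken for it. Genes with the 8-base match to the miR-34a-3p seed, GCTGATTA, differed from genes with none by -0.03667 (132 genes, 95% interval -0.1018 to 0.03266, permutation p = 0.32). That interval leaves a weak effect open. The 7-base words of miR-34a-3p, CTGATTA (z = -0.19, 1435 genes) and GCTGATT (z = 0.24, 1429 genes), lay near the middle of the 16371 words. The words of the guide had -9.73 and -7.81, so repression through the miR-34a-3p seed as strong as the guide's was not seen. An opposite strand of another sequence was not tested. A seed in the scrambled control would raise its targets in this comparison, but the most positive score of any 7-base word was 4.315 (GAGGGGC), under the 6 set for it, so no such seed was seen.

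The interferon response genes that fell may be direct targets. A 7- or 8-base seed match lay in 5 of the 6 that fell (CXCL10, EPSTI1, IFIT1, HERC6 and OAS3, but not MX1) and in 6 of the other 31 (83.3% against 19.4%; Fisher's exact p = 0.00537, 2-sided). Of the 5, CXCL10 held an 8mer and the other 4 a 7mer-m8, a class with a small mean difference from genes with no match (-0.01, or -0.07 with length and GC content of the 3' UTR removed). This is a hypothesis found and tested on the same genes. The 6 genes are those called with all 8 libraries, 2 were called without mimic library 2 and 23 without mimic library 4, and the test counts genes as independent although they varied together (estimated correlation 0.884).

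Genes were also grouped by the letters of their symbol, which is a rough guide to families. Of 236 groups of at least 8 tested genes, camera called 35, 12 up and 23 down, and 0 with an estimated correlation (smallest adjusted p = 0.293). Ribosomal protein genes leaned down, with 31 of 48 RPL genes fallen and none risen (median -0.15, adjusted p = 4.7e-06) and 20 of 31 RPS genes fallen and 1, the paralog RPS27L, risen (median -0.14, kinases and other genes whose symbols begin alike left out). Nucleoporins (17 of 22 NUP genes fell, none rose) and HSPA genes (9 of 14 fell, none rose) did too. Collagens leaned up, 11 of 29 risen and 1 fallen, with COL4A1, COL4A2, COL5A1, COL5A2 and COL18A1 among the risen. Intraflagellar transport genes did as well, 7 of 14 risen and none fallen, IFT88 by 0.67. These directions held with RLE, upper-quartile and library-size scaling.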
